A study of Drosophila melanogaster with 14 samples.

How the data were processed

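RNA was measured in whole guts of adult male Drosophila melanogaster. Transgenes were driven in intestinal progenitor cells by esg-Gal4 under a temperature-sensitive repressor. Flies spent 8 to 14 days at 18 °C and then 2 days at 29 °C, the temperature that releases the driver. Each sample pooled 15 guts, and 200 ng of RNA was labelled with Cy3 and hybridised to a 1-colour Agilent array. The 14 arrays fall into 4 groups: lacZ RNAi (2 arrays), Dph5 RNAi (4), Ras[V12] with lacZ RNAi (4) and Ras[V12] with Dph5 RNAi (4). The lacZ construct targets a gene that flies lack and serves as the RNAi control. Dph5 encodes a methyltransferase of diphthamide synthesis, the modification of a histidine of elongation factor eEF2. The study description gives 4 samples per group, and further lacZ RNAi samples were not analysed here. The labels say only that the samples are separate, so p-values measure the spread between these samples, which is biological only as far as the samples are separate pools of flies.

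Per the file headers, the scanner values are fluorescence intensity from Agilent Feature Extraction 10.7.3.1, background-subtracted and detrended within each array, with no scaling between arrays. The authors' combined table holds log2 values. Set against the scanner values, each of its 14 columns was the log2 processed signal minus the array's 75th percentile, centred per probe on the median of the arrays, and 100.0% of probes lay within 0.1 log2 of that. Per the file headers, other columns are scanner flags of 0 or 1. Spots flagged as uneven or as population outliers were dropped here. The flag for signal well above background served to filter probes, and saturated spots were only counted.

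Values were recomputed from the scanner intensities. Flagged spots were dropped, spots of 1 probe were combined, and log2 processed signal minus the array's 75th percentile was used. Of 32162 probes, 32156 had an unflagged spot on every array. Probes were tested if well above background on every array of at least 1 group, with 1 probe per target identifier, the one with the highest mean of the 4 group means. This left 16964 targets. Gene symbols came from RefSeq accessions, cDNA clones and FlyBase transcripts in the reference gene table, and only 332 of 25763 identifiers (1.29%) could be named, 221 of them among the tested targets. The remaining targets were counted but not named, so a gene can be counted under more than 1 identifier. Names through a cDNA clone are less certain than those through an accession.

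The arrays' 75th percentile of processed signal ranged from 644 to 849 intensity units, and 63.5 to 69.0% of probes were well above background. From 73 to 144 spots per array were flagged and 0 were saturated. The median SD of log2 signal over repeated spots of a probe was 0.06 to 0.09. The number of arrays limits the precision, most of all for lacZ RNAi.

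Groups were compared with limma 3.58.1 (lmFit and eBayes) in R 4.3.3 with data.table (version 1.17.8), in 1 model with a mean per group over all 14 arrays. The 5 contrasts were Ras[V12] against none under each RNAi construct, Dph5 against lacZ RNAi with and without Ras[V12], and the interaction. Tests were two-sided, with Benjamini-Hochberg adjustment over all tested targets and a threshold of 0.05. Counts at a log2 fold change of at least 1 in size, a 2-fold difference, stand beside the full counts. Tables and plots used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. Genes were named by a rule: Dph5 and Ras85D first, then per contrast the 10 highest and 10 lowest log2 fold changes (5 and 5 for the interaction) among called targets with a symbol other than a CG or CR number, a difference of at least 2-fold, signal in both groups and no overlap between their arrays, and up to 4 members of each gene list. The groups, contrasts, rule, gene lists and most alternatives were fixed before the data were examined. Neither Dph5 nor Ras85D has a named probe, so knockdown and Ras[V12] expression could not be checked. Of 26 lists fixed for the gut, its cell types, neighbouring tissues, signalling and translation, 8 had a tested member, with 3 at most and 11 in all. No list reached the 5 members set for a test of lists, so limma's camera and fry were not run.

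The pipeline was tested on simulated data, with 200 of 16964 targets changed. Changes of log2 1 were recovered in 70.1% of targets for Ras[V12] with lacZ RNAi, 73.1% for Dph5 RNAi alone, 85.1% for Dph5 RNAi with Ras[V12] and 83.6% for Ras[V12] with Dph5 RNAi. False calls numbered 5 of 138, 15 of 147, 8 of 163 and 6 of 165 in that order, so in its draw those for Dph5 RNAi alone exceeded the nominal rate. Each contrast had a single draw, with far fewer changed targets than limma called on the real arrays, so these rates need not carry over.

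The return of Ras[V12] changes under Dph5 RNAi was counted over targets called in the Ras[V12] contrast with lacZ RNAi. The share of the log2 change kept is Ras[V12] with Dph5 RNAi minus lacZ RNAi, divided by Ras[V12] with lacZ RNAi minus lacZ RNAi. Since both comparisons share the arrays of Ras[V12] with lacZ RNAi, the covariance of the fold changes was set against 100 simulated draws without effects, and the count was repeated with those arrays split into separate pairs. Arrays came from 2 slides, with every group on both and each group in its own column, so a column effect cannot be separated from the group. Alternatives were normexp background (offset 50), quantile normalization, the authors' values, other filters on dim probes, the mean of all probes, slide or replicate number as a block, each slide alone, only the compared groups, a variance trend, array weights, and each array left out. Normexp used the median spot signal, as the mean spot signal planned for it was not used here. Median centring was added after the data were seen.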

Results

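RNA of whole guts was profiled on 14 arrays in 4 groups, combining oncogenic Ras[V12] or none with RNAi against Dph5 or the lacZ control. Within a group, pairs of arrays had Pearson r from 0.987 to 0.995 across probes, which are not independent replicates, and median absolute log2 differences from 0.11 to 0.18. Positions are those of release 6 of the genome: LysB lies on chromosome 3L from 1207371 to 1207981, kek1 on 2L from 12817000 to 12822787, bwa on 2L from 20066391 to 20073719, NimC3 on 2L from 14019357 to 14020208, and Ugt303A1 on 3R from 11175529 to 11177910. All are protein-coding genes.

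The comparison of Ras[V12] with no Ras[V12] under lacZ RNAi asks what oncogenic Ras in progenitors changes in the gut. The transcript of bwa, an alkaline ceramidase, rose 7.88-fold with Ras[V12] (log2 fold change 2.98 ± 0.11 SE, 4 against 2 arrays). Pa1 rose 4.74-fold (2.25 ± 0.12), and Pde1c, a cyclic nucleotide phosphodiesterase, 4.57-fold (2.19 ± 0.26). U12, a small nuclear RNA of the minor spliceosome, rose 4.23-fold (2.08 ± 0.15), and the membrane skeleton gene alpha-Spec 2.63-fold (1.40 ± 0.07). Ugt303A1, a UDP-glycosyltransferase, fell 17.8-fold (-4.15 ± 0.14), and NimC3, of the Nimrod family of receptors, 7.72-fold (-2.95 ± 0.27).

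Other genes named by the rule as higher were the minor spliceosome RNA U11, GramD1B, CycY (cyclin Y), mRpL14 of the mitochondrial ribosome and vsg, at log2 fold changes from 1.21 to 1.88. U11 was well above background on only 1 of 2 lacZ RNAi arrays. Those named as lower also held fend (-2.32), the alkaline phosphatase Alp13 (-2.21), Tango14 (3.99-fold lower), ptc, the Hedgehog receptor (-1.80), and nwk, a synaptic adaptor (-1.74). nwk was well above background on 1 of 4 arrays with Ras[V12]. Under normexp background the values were smaller for U12 (0.91), U11 (0.38), vsg (0.74), NimC3 (-1.14), Tango14 (-0.76), ptc (-1.02) and nwk (-0.38), and each still passed.

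Of the 11 tested members of the fixed lists, 2 rose, 7 fell and 2 did not pass, with equal counts when adjusted over the list alone. Both digestive lysozymes fell, LysB 6.82-fold (-2.77 ± 0.21) and LysE 5.49-fold (-2.46 ± 0.17); they are close paralogs, and their probes were not shown to tell them apart. Falls were also seen for the gut serine protease Jon65Aiii (-0.69 ± 0.12), the zinc transporter Zip42C.2 of the Malpighian tubule list (-1.75 ± 0.35) and eIF3l, a subunit of an initiation factor (-0.38 ± 0.09). Among ribosomal proteins, RpS29 fell (-0.73 ± 0.13), while RpS18 (-0.23) and RpL23 (-0.27, not passing) turned positive under quantile normalization, at 0.11 and 0.14. RpL23 passed when only the compared groups were fitted (-0.27). The RpS18 call also ended without lacZ RNAi replicate 1 (-0.17) and under median centring (-0.09). chrb, an inhibitor of TOR signalling, rose 2.25-fold (1.17 ± 0.11), and the EGFR target kek1 gave 0.02 ± 0.30, with a sign that turned under other settings. The Notch target E(spl)mbeta-HLH passed narrowly (0.71 ± 0.29). The call ended without lacZ RNAi replicate 1 (0.39), and also without Dph5 RNAi replicate 3 or 4, Ras[V12] lacZ RNAi replicate 1, 3 or 4, or Ras[V12] Dph5 RNAi replicate 1 or 3 (0.58 to 0.73), and under normexp background (0.33). With slide (0.71) or replicate number (0.68) as a block it ended too, as it did with array weights, without a filter on dim probes and with only the compared groups (0.71 each). On slide 1 alone the calls of nwk (-1.61), Jon65Aiii (-0.50), RpS18 (-0.27) and E(spl)mbeta-HLH (0.81) ended, and on slide 2 alone those of vsg (1.41), ptc (-1.54), eIF3l (-0.37) and RpS18 (-0.18). Smaller values that still passed were those of Jon65Aiii (-0.26) and RpS29 (-0.42) under quantile normalization, eIF3l under median centring (-0.24) and chrb with the mean of all probes (0.68).

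In all, limma called 11707 of 16964 targets (69.0%), 5052 higher and 6655 lower, and 1982 higher and 3078 lower by at least 2-fold. Slide 1 alone gave 8976 and slide 2 alone 9290. The arrays of both groups did not overlap for 75.04% of targets, where chance gives 13.3%. The median log2 fold change of all targets was -0.15, and -0.01 under quantile normalization or median centring, where 50.5% and 51.5% of calls were higher in place of 43.2%, so the balance of directions depends on the scaling.

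**Figure D1:**
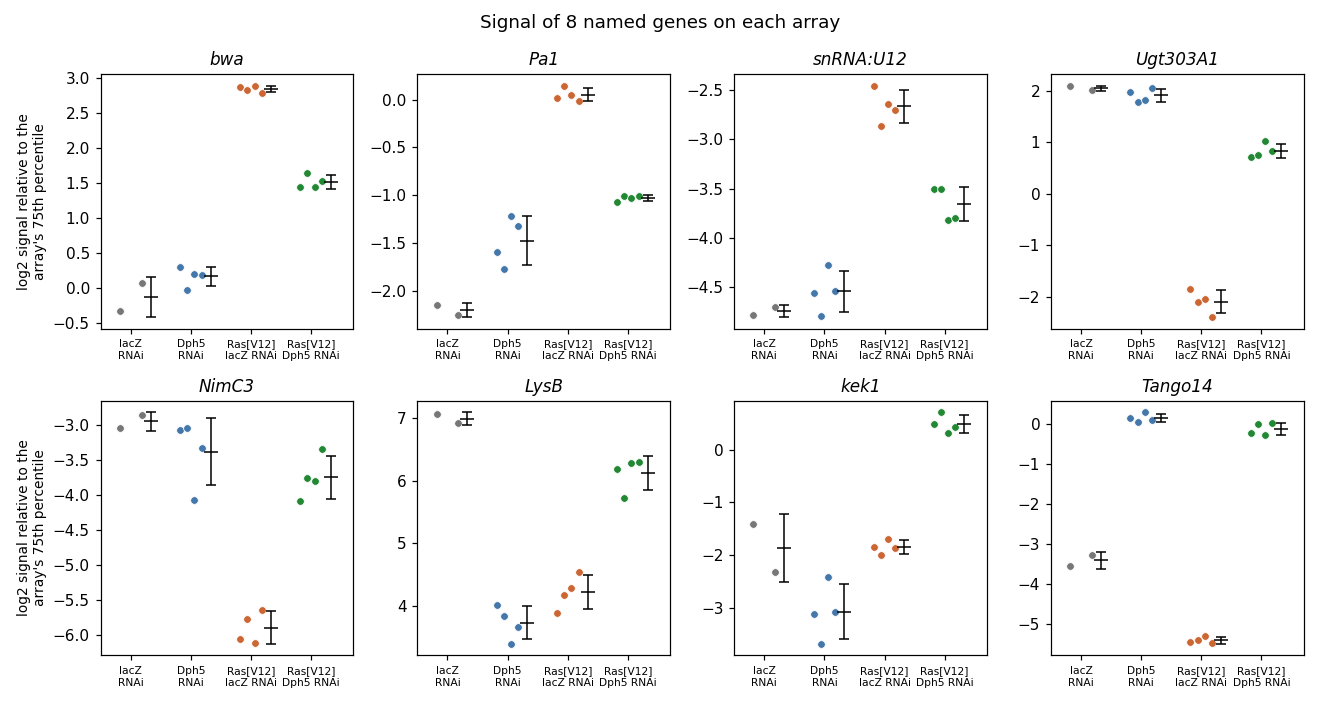
Log2 signal relative to the array's 75th percentile (y axis) for 8 named genes in the 4 groups (x axis). Points are arrays, and bars are the group mean ± SD (n = 2 for lacZ RNAi, 4 for the others). Ugt303A1 averaged 2.05 with lacZ RNAi, -2.10 with Ras[V12] and lacZ RNAi, and 0.83 with Ras[V12] and Dph5 RNAi.

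Comparing Dph5 with lacZ RNAi in the presence of Ras[V12] asks what loss of this diphthamide enzyme does to the Ras[V12] gut. Tango14 was 38.9-fold higher with Dph5 RNAi (log2 fold change 5.28 ± 0.09 SE, 4 against 4 arrays). Ugt303A1 rose 7.60-fold (2.93 ± 0.11), NimC3 4.43-fold (2.15 ± 0.22) and LysB 3.73-fold (1.90 ± 0.17). kek1, a transmembrane inhibitor of EGFR and a target of its signalling, rose 5.06-fold (2.34 ± 0.24). GramD1B fell 3.04-fold (-1.61 ± 0.22), Unc-76, an adaptor of axonal transport, 2.91-fold (-1.54 ± 0.12), and bwa 2.52-fold (-1.33 ± 0.09).

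The rule also named nwk (2.27), LysE (1.70), the chitin-binding gene obst-B (1.29) and ptc (1.27) as higher. nwk was well above background on only 1 of 4 arrays with Ras[V12] and lacZ RNAi, so the size of its rise is uncertain. Under normexp background nwk (0.43), NimC3 (0.66), Tango14 (3.22), ptc (0.70), obst-B (0.54), U11 (-0.36) and MCU (-0.68) were smaller and still passed. U11 (-1.22), the mitochondrial calcium uniporter MCU (-1.17), Pde1c (-1.12) and Pa1 (-1.08) were lower. Of the 11 list members, 3 rose (kek1, LysB and LysE) and 4 fell, also when adjusted over the list alone. eIF3l (-0.67 ± 0.07) and chrb (-0.55 ± 0.09) fell. The falls of RpL23 (-0.36 ± 0.13) and RpS18 (-0.17 ± 0.05) were small. RpS29 went the other way without passing, from a mean of -4.42 with lacZ RNAi to -4.20 with Dph5 RNAi. It was called higher without Ras[V12] lacZ RNAi replicate 1 (0.29). The RpL23 call ended under quantile normalization (-0.31) and without Ras[V12] lacZ RNAi replicate 1 (-0.34) or 2 (-0.33) or Ras[V12] Dph5 RNAi replicate 2 (-0.29) or 3 (-0.26). That of RpS18 ended under normexp background (-0.16) and without Ras[V12] Dph5 RNAi replicate 3 (-0.14). On slide 1 alone U11 (-1.29), chrb (-0.42), RpL23 (-0.40) and RpS18 (-0.17) did not pass, and on slide 2 alone ptc (0.91), RpL23 (-0.32) and RpS18 (-0.18) did not. With the mean of all probes chrb gave -0.36 and still passed.

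Here limma called 9680 targets (57.1%), 4672 higher and 5008 lower, with 1616 higher and 1104 lower by at least 2-fold. Slide 1 alone gave 6805 and slide 2 alone 6936. For 56.0% of targets the arrays of both groups did not overlap, where chance gives 2.86%.

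The genes that the rule named for Ras[V12] under lacZ RNAi were then followed when Dph5 RNAi was added. bwa, Pa1, Pde1c, U12, U11, GramD1B, alpha-Spec and CycY had risen with Ras[V12] and fell when Dph5 RNAi was added. Ugt303A1, NimC3, LysB, LysE, ptc and nwk had fallen and rose. Tango14 had also fallen with Ras[V12], but on adding Dph5 RNAi rose from a mean of -5.41 to -0.13, above its mean of -3.41 with lacZ RNAi alone. The others did not pass: mRpL14 (-0.25 ± 0.11), vsg (-0.33 ± 0.23), Alp13 (0.18 ± 0.27), Zip42C.2 (0.60 ± 0.29) and fend (-0.59 ± 0.31). Zip42C.2 did pass without Ras[V12] lacZ RNAi replicate 3 (0.86) or Ras[V12] Dph5 RNAi replicate 1 (0.82).

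Of the 11707 targets called with Ras[V12], limma called 7130 (60.9%) in the opposite direction on adding Dph5 RNAi and 604 in the same direction. This held for 3573 of 5052 raised and 3557 of 6655 lowered targets, against 1491 and 1833 if the calls were independent. They are not, as both comparisons share arrays, so opposite calls arise more often than that without any effect. The median share of the log2 change kept was 52.1%, 42.1% for raised and 60.8% for lowered targets. Its SD was 2.83 over the 4 Ras[V12] Dph5 RNAi arrays, with the means of the other groups held fixed, so their spread is left out. Of 5060 targets changed at least 2-fold, 3649 (72.1%) went the opposite way and 136 the same way, and 48.4% was kept (SD 3.91, n = 4). At 2-fold the share kept was 43.0% for raised and 52.5% for lowered targets, a smaller gap. The covariance of both fold changes was -0.95 over all targets, against -0.02 in simulated draws with shared arrays and no effects. Pearson r across targets, which are not independent, was -0.74, against a mean of -0.41 and a lowest value of -0.46 in those draws. Slide 1 alone gave 4916 opposite calls (54.8%) and slide 2 alone 5081 (54.7%).

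**Figure D2:**
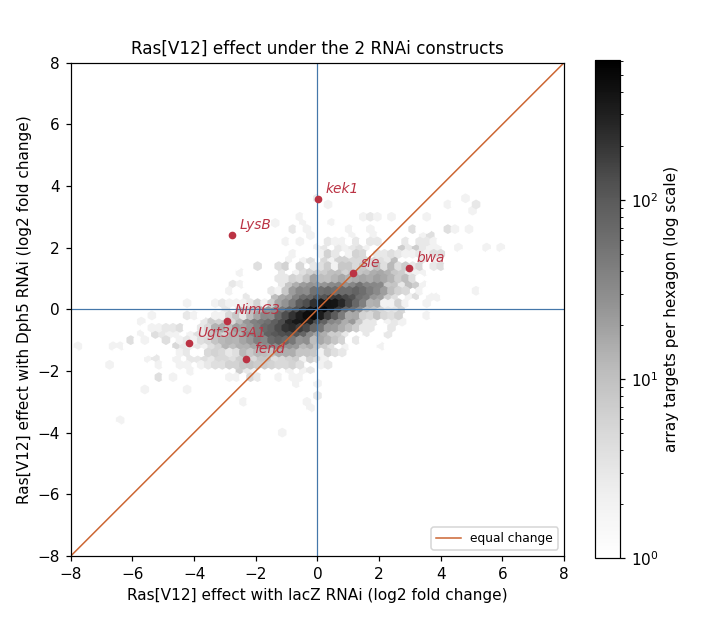
Log2 fold change with Ras[V12] under lacZ RNAi (x axis) and under Dph5 RNAi (y axis) for the tested targets, shaded by their number per hexagon on a log scale, with 7 named genes as red points. The orange line marks equal changes, 33 targets lie outside the axes, and the slope of y on x is 0.363.

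Dph5 against lacZ RNAi without Ras[V12] asks what the knockdown does to an otherwise unchanged gut. Tango14 was 11.7-fold higher with Dph5 RNAi (log2 fold change 3.55 ± 0.11 SE, 4 against 2 arrays). LysB fell 9.61-fold (-3.27 ± 0.21) and LysE 6.58-fold (-2.72 ± 0.17). Alp13 fell 3.20-fold (-1.68 ± 0.33), and kek1 2.31-fold (-1.21 ± 0.30). fend was also called lower (-1.30 ± 0.38). bwa (0.30 ± 0.11), Ugt303A1 (-0.14 ± 0.14) and NimC3 (-0.43 ± 0.27) did not pass.

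Several of these calls ended when 1 array was left out. Without lacZ RNAi replicate 1, Alp13 (-1.57) and kek1 (-0.75) did not pass. Neither did Alp13 on slide 1 (-2.10) or slide 2 (-1.26) alone, kek1 on slide 2 alone (-0.42), or fend on slide 1 (-1.44) or slide 2 (-1.16) alone. kek1 under normexp background (-0.79) and fend with the mean of all probes (-0.67) were smaller and passed. The kek1 call ended when only the compared groups were fitted (-1.21). That of fend ended with array weights (-1.30), the replicate block (-1.09) and no filter on dim probes (-1.30). The fend call ended without lacZ RNAi replicate 1 (-1.14) or 2 (-1.46), Dph5 RNAi replicate 2 (-1.22), 3 (-1.27) or 4 (-1.31), or Ras[V12] Dph5 RNAi replicate 1 or 2 (-1.30). Of the 11 list members, limma called 0 higher, also at an unadjusted p of 0.05, and 4 lower (LysB, LysE, kek1 and eIF3l), as when adjusted over the list alone. The eIF3l value of -0.29 ± 0.09 passed with all arrays, but not without any of lacZ RNAi replicates 1 and 2, Dph5 RNAi replicates 1, 2 and 4, Ras[V12] lacZ RNAi replicates 2, 3 and 4, and Ras[V12] Dph5 RNAi replicates 1, 2 and 3 (-0.35 to -0.24). Nor did it pass with only the compared groups or no filter on dim probes (-0.29 each), array weights (-0.30) or the replicate block (-0.25). The same held on slide 1 (-0.33) or slide 2 (-0.26) alone. For fend and eIF3l, leaving out an array with Ras[V12] did not change the value, only the shared spread and the adjustment.

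For Dph5 RNAi alone limma called 2880 targets (17.0%), 1324 higher and 1556 lower, with 376 higher and 347 lower by at least 2-fold, and the arrays did not overlap for 37.7% of targets, where chance gives 13.3%. The count was 1303 without lacZ RNAi replicate 1, 581 on slide 1 alone, 793 on slide 2 alone and 963 when only the compared groups were fitted.

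Ras[V12] against no Ras[V12] under Dph5 RNAi asks what oncogenic Ras still changes when Dph5 is knocked down. kek1 rose 11.9-fold (log2 fold change 3.57 ± 0.24 SE, 4 against 4 arrays), LysB 5.26-fold (2.39 ± 0.17) and LysE 3.90-fold (1.96 ± 0.14). bwa rose 2.55-fold (1.35 ± 0.09) and the nucleolar gene sle 2.28-fold (1.19 ± 0.08). fend fell 3.04-fold (-1.60 ± 0.31), Zip42C.2 2.60-fold (-1.38 ± 0.29), Pgant8, a mucin-type glycosyltransferase, 2.39-fold (-1.26 ± 0.15), and Ugt303A1 2.12-fold (-1.09 ± 0.11). U11 was called higher (1.14 ± 0.27), but not under normexp background (0.03), and was well above background on 1 of 4 arrays with Dph5 RNAi alone.

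Of the 11 list members, 4 rose and 6 fell, also when adjusted over the list alone. chrb rose (0.46 ± 0.09) beside kek1 and both lysozymes. eIF3l fell (-0.76 ± 0.07), as did Zip42C.2. Jon65Aiii (-0.51 ± 0.10), RpL23 (-0.59 ± 0.13), RpS18 (-0.30 ± 0.05) and RpS29 (-0.33 ± 0.10) were called lower, but under quantile normalization none of these 4 passed, at -0.09, -0.21, -0.0046 and -0.12. On slide 1 alone Jon65Aiii (-0.56), RpL23 (-0.45), RpS18 (-0.27) and RpS29 (-0.40) did not pass, and on slide 2 alone U11 (0.77), Zip42C.2 (-1.06), RpS18 (-0.34) and RpS29 (-0.26) did not. Smaller values that passed were those of fend (-0.98) and Pgant8 (-0.81) under normexp background and chrb with the mean of all probes (0.24). E(spl)mbeta-HLH gave 0.19 ± 0.24 and did not pass.

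Here limma called 9297 targets (54.8%), 3883 higher and 5414 lower, with 808 higher and 1050 lower by at least 2-fold, and 51.3% had arrays that did not overlap, where chance gives 2.86%. Slide 1 alone gave 6081 and slide 2 alone 5161, and under quantile normalization 52.9% of calls were higher in place of 41.8%.

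The interaction asks whether the Ras[V12] effect itself differed between both RNAi constructs. It was positive for LysB (5.16 ± 0.27 log2, SE) and LysE (4.42 ± 0.22), which fell with Ras[V12] under lacZ RNAi and rose with it under Dph5 RNAi. kek1 (3.55 ± 0.38) rose under Dph5 RNAi, while Ugt303A1 (3.07 ± 0.18) fell less and NimC3 (2.58 ± 0.35) did not pass there. It was negative for Pa1 (-1.80 ± 0.16), bwa (-1.63 ± 0.15), Pde1c (-1.23 ± 0.33) and U12 (-1.19 ± 0.19), whose rises were smaller under Dph5 RNAi, and for U2:34ABb, an RNA of the major spliceosome (-1.07 ± 0.27).

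Of the 11 list members, 3 had a positive interaction (LysB, LysE and kek1) and 2 a negative one (chrb and eIF3l), as when adjusted over the list alone. That of chrb was -0.71 ± 0.14. The eIF3l value of -0.38 ± 0.12 did not pass without lacZ RNAi replicate 2 (-0.32) or on slide 1 (-0.33) or slide 2 (-0.42) alone. On slide 1 alone U12 (-0.95), U2:34ABb (-0.75) and chrb (-0.73) did not pass, nor did Pde1c on slide 2 alone (-1.23). Under normexp background NimC3 (0.89) and U12 (-0.65) were smaller and still passed, as was chrb with the mean of all probes (-0.43). limma called 7343 targets (43.3%), 3732 positive and 3611 negative, with 1719 and 1143 of at least log2 1 in size, and slide 1 alone gave 3808 and slide 2 alone 4352.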

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

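Of the tests of explanations in this part, those other than the counts over other splits of the arrays were chosen only after the result was seen, as were the genes with CG numbers, the antisense RNA, the snoRNA and the lncRNAs.

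limma's interaction test, of whether the Ras[V12] effect differed between both RNAi constructs, called 7343 targets and 31 of the genes reported, 13 with a positive and 18 with a negative interaction. Positive log2 values were 5.16 for LysB, 4.42 for LysE, 3.55 for kek1, 3.43 for CG15254, 3.26 for CG17633, 3.07 for Ugt303A1, 2.58 for NimC3, 2.56 for CG9672, 1.86 for Alp13, 1.73 for Tango14, 1.63 for nwk, 0.93 for obst-B and 0.38 for snoRNA:Psi28S-2566. Negative values were -3.12 for lncRNA:alphagamma-element:CR32865, -1.80 for Pa1, -1.71 for CG6484, -1.63 for bwa, -1.23 for Pde1c, -1.19 for U12, -1.07 for U2:34ABb, -1.05 for CycY, -1.02 for Unc-76, -1.002 for GramD1B, -0.92 for MCU, -0.86 for alpha-Spec, -0.83 for lncRNA:roX2, -0.71 for chrb, -0.48 for mRpL14 and -0.38 for eIF3l. For 2 of the negative ones the fitted value does not measure the difference: asRNA:Eig63F-2 (-6.59) was not well above background in any group but Dph5 RNAi, so it has no measured Ras[V12] effect under lacZ RNAi, and CG34423 (-2.28) was not well above background on the lacZ RNAi arrays.

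Several of these interactions did not pass when 1 array was left out or under other settings. Without lacZ RNAi replicate 1 these were obst-B (0.88), snoRNA:Psi28S-2566 (0.36) and lncRNA:roX2 (-0.71). Without lacZ RNAi replicate 2 they were GramD1B (-0.72), mRpL14 (-0.33), nwk (1.27), MCU (-0.81), eIF3l (-0.32), CG6484 (-1.08) and snoRNA:Psi28S-2566 (0.39). GramD1B was also lost without Ras[V12] lacZ RNAi replicate 2 (-0.94) or Ras[V12] Dph5 RNAi replicate 1 (-0.90) or 3 (-0.98), and nwk without Ras[V12] lacZ RNAi replicate 3 (1.52) or Ras[V12] Dph5 RNAi replicate 3 (1.55). mRpL14 was lost without Dph5 RNAi replicate 2, 3 or 4, Ras[V12] lacZ RNAi replicate 3 or 4, or Ras[V12] Dph5 RNAi replicate 1 or 2 as well (-0.49 to -0.41). Under normexp background Alp13 (1.23), Tango14 (0.52), NimC3 (0.89), U12 (-0.65) and lncRNA:alphagamma-element:CR32865 (-1.997) were smaller and passed, while nwk (0.25), obst-B (0.35) and CG34423 (-0.33) did not pass, nor did mRpL14 under quantile normalization (-0.40), snoRNA:Psi28S-2566 under median centring (0.31) and lncRNA:roX2 with the mean of all probes (-0.65). GramD1B and mRpL14 were lost without a filter on dim probes (-1.002 and -0.48), and GramD1B (-0.90), nwk (1.68) and snoRNA:Psi28S-2566 (0.36) with the replicate block. On slide 1 alone, with fewer arrays, GramD1B (-0.50), mRpL14 (-0.26), CG6484 (-0.76), CG34423 (-1.45), snoRNA:Psi28S-2566 (0.55), Alp13 (2.13), nwk (1.73), obst-B (0.75), Unc-76 (-0.93), MCU (-0.88), U12 (-0.95), U2:34ABb (-0.75), chrb (-0.73), eIF3l (-0.33) and lncRNA:roX2 (-0.78) did not pass. On slide 2 alone it was GramD1B (-1.51), snoRNA:Psi28S-2566 (0.20), Alp13 (1.59), nwk (1.52), obst-B (1.10), MCU (-0.96), Pde1c (-1.23), eIF3l (-0.42) and lncRNA:roX2 (-0.88).

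In 5 of 150 sets of values, each of 1 reported quantity in 1 group, 1 array stood apart from the rest of its group. Chance gives about 1 in 20, so these are no more than chance alone would give. The gap as a share of the group's range was 0.982 for Pgant8 in Dph5 RNAi replicate 3 (-2.39 against -2.15 to -2.14), 0.91 for lncRNA:roX1 in Ras[V12] lacZ RNAi replicate 2 (4.22 against 4.40 to 4.42), 0.901 for CG34423 in Ras[V12] lacZ RNAi replicate 1 (-3.28 against -3.62 to -3.58), 0.875 for LysE in Dph5 RNAi replicate 3 (4.15 against 4.60 to 4.66) and 0.852 for eIF3l in Ras[V12] Dph5 RNAi replicate 4 (1.04 against 1.23 to 1.26).

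A random division of the arrays is argued against in both comparisons of 4 with 4 arrays, but not excluded. Only the real one of 35 splits gave as many called targets for Dph5 RNAi with Ras[V12] (9680, highest other 1) and likewise 1 of 35 for Ras[V12] with Dph5 RNAi (9297, highest other 4). This is the smallest share that 35 splits can give. Every other split mixes arrays of both groups, which widens the spread within each part, so low counts there were likely from the start.

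The partial return of Ras[V12] changes under Dph5 RNAi is not accounted for by random deviations of the arrays that both comparisons share, since with separate Ras[V12] arrays at least 55.6% of targets still went the opposite way. An effect common to all Ras[V12] lacZ RNAi arrays, such as one of their column, would stay in both parts of the split and could not be excluded. If the gut had lost the same share of Ras[V12] tissue for every target, values should lie between those of Dph5 RNAi and Ras[V12] with lacZ RNAi. Of the targets changed at least 2-fold, 236 of 5060 (4.66%) lay outside both. This was below the bound of 5% first set for these targets and went the way of this explanation. Over all tested targets 1892 of 16964 (11.2%) lay outside both, but most of those were not changed 2-fold by Ras[V12], and the bound was not set for them. A target with its own response to Dph5 RNAi may lie outside both even under this explanation, so these counts decide little. A criterion added after that, equal shares kept on the linear scale, argues against it: the median kept was 24.1% for raised and 47.3% for lowered targets, and the gap was at least 16.6 percentage points over 3 scalings and 2 slides. This share is the Ras[V12] effect under Dph5 RNAi over that under lacZ RNAi, so its baselines differ from those of the log2 share given above. As the criterion was chosen once the first had gone the other way, it does not settle the question. Fewer Ras[V12] cells together with changed expression in the cells that remain, or lower output of the Ras[V12] transgene, may each give such a return. Neither was tested, since whole guts were profiled and Ras85D has no named probe.

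Large differences with Dph5 RNAi were in part shared with and without Ras[V12]: of 57 targets at least 8-fold apart without Ras[V12], 26 (45.6%) were called the same way with it. Over all tested targets limma called 57.1% for Dph5 RNAi with Ras[V12] and 17.0% without it, in either direction. Of 1839 targets called in both, 1184 went the same way. These were 608 higher and 576 lower, against 365 and 459 if the calls were independent. Of 307 at least 8-fold apart with Ras[V12], 49 (16.0%) were called the same way without it. At least 8-fold apart in both were 10 targets, 8 higher and 2 lower. Most large differences thus lacked a call the same way in the other comparison. A missing call does not show that a difference was absent, least of all without Ras[V12], where lacZ RNAi had only 2 arrays. Both the genetic background of the Dph5 RNAi line and the knockdown of Dph5 predict shared differences, and the bound of 50% set for each was wrong by design, since line and knockdown sit in the same flies and either may act differently with Ras[V12]. For these targets the 2 explanations cannot be told apart, and another RNAi line would be needed.

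Replicate 1 of Ras[V12] with lacZ RNAi had 346 tested targets more than 1 log2 above the rest of its group, against 84 to 169 in the other 3 arrays, 184 to 256 with Dph5 RNAi, 84 to 197 with Ras[V12] and Dph5 RNAi, and 346 and 309 for the lacZ RNAi arrays, each set against only 1 other, and 69.0% of its probes were well above background. Targets known from adult testis cDNA clones were raised 6.17 times as often as other clones among tested targets (4 of 52 against 4 of 321, Fisher's exact test, two-sided p = 0.0154), which does not set this array apart, as Dph5 RNAi replicate 2 reached a ratio of 9.26 (3 of 52, two-sided p = 0.0209) and Ras[V12] lacZ RNAi replicate 4 had 2 of 52 against 0 of 321 (two-sided p = 0.0191). Widened to all targets, since the filter drops those seen on 1 array alone, the ratio was 19.7 (48 of 139 against 7 of 399, Fisher's exact test, two-sided p = 2.55e-24), with 8 of 139 the highest on another array, so the share raised set it apart more than the ratio, which was 17.2 on Ras[V12] lacZ RNAi replicate 4 (6 of 139 against 1 of 399). Targets read on 1 array are not independent, so the p-values of Fisher's exact test here measure no spread between samples. Over all targets scaling of the array is argued against, as 43 of 139 stayed raised after quantile normalization (ratio 30.9), while the tested targets decide nothing, with 6.17 (3 of 52) against 18.5 (3 of 52) on Ras[V12] lacZ RNAi replicate 4. RNA from testis in that sample may account for it but stays open, as the libraries were chosen after the excess was seen and no gene of the fixed male germline list is named on the array; no biological explanation was tested.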

How the results depend on the processing

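Median centring was chosen only after the data were seen; the other alternatives here were planned. For 161 gene results and 4463 alternatives, 4220 kept their direction and side of the threshold, 228 kept direction but no longer passed, 5 newly passed and 10 reversed; for none of these was the cause tested. Reversed log2 values were, for kek1 with Ras[V12] and lacZ RNAi, -0.0247 under normexp, -0.51 on slide 1, -0.0754 with the replicate block, -0.44 without lacZ RNAi replicate 2 and -0.0321 without Ras[V12] lacZ RNAi replicate 3 (-0.44 to 0.48 over all arrays left out in turn). Under quantile normalization they were 0.14 for RpL23 and 0.11 for RpS18 with Ras[V12] and lacZ RNAi. For E(spl)mbeta-HLH with Ras[V12], Dph5 against lacZ RNAi, they were 0.39 on slide 1, 0.0368 without Ras[V12] lacZ RNAi replicate 4 and 0.0061 without Ras[V12] Dph5 RNAi replicate 4 (-0.22 to 0.0368 over arrays left out in turn). Slide 2 alone gave -0.58 for that E(spl)mbeta-HLH comparison, where it newly passed. Counts that moved by over 1.5 times, cause not tested: under normexp background the 2-fold counts were 2745 for Ras[V12] with lacZ RNAi, 1460 for Dph5 RNAi with Ras[V12], 252 for Dph5 RNAi alone, 783 for Ras[V12] with Dph5 RNAi, 1644 for the interaction and 2343 for the return, with 57.0% of the change kept (43.0% at 2-fold). Without a filter on dim probes 59.5% was kept (52.5% at 2-fold). With only probes well above background on all arrays, where fewer targets are tested, 2-fold counts were 454 for Dph5 RNAi alone and 1211 for Ras[V12] with Dph5 RNAi. With fewer arrays, slide 1 gave 581 for Dph5 RNAi alone (447 at 2-fold), 6081 for Ras[V12] with Dph5 RNAi and 3808 for the interaction, slide 2 gave 793, 5161 and 4352, and the compared groups alone gave 963 (468 at 2-fold) for Dph5 RNAi alone. Array weights gave 1665 for Dph5 RNAi alone. Of the calls for Dph5 RNAi alone, 57.8% on slide 1 and 66.6% on slide 2 were higher, in place of 45.97%. Leaving out each array gave 10390 to 11739 for Ras[V12] with lacZ RNAi (4908 to 5079 at 2-fold), 8912 to 9818 for Dph5 RNAi with Ras[V12] (2593 to 2749), 1303 to 2771 for Dph5 RNAi alone (539 to 757, lowest without lacZ RNAi replicate 1), 8314 to 9396 for Ras[V12] with Dph5 RNAi (1733 to 1965), 6389 to 7302 for the interaction (2730 to 2941), 6653 to 7148 for the return (3467 to 3672) and 51.2 to 53.2% kept (47.2 to 50.2%); a lone lacZ RNAi array is then assumed to vary like the other groups. With replicate number as a block the 5 counts were 11367, 9517, 1995, 9100 and 6959; arrays of the same number resembled each other most in only 4 of 12 pairings (r of deviations -0.12 to 0.18, across targets, which are not independent), so the numbers were not used as pairs. Tests of gene lists were not run, as none had 5 tested members. Genes near background, such as U11, nwk, CG34423 and asRNA:Eig63F-2, are limited by signal over background.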

Other observations

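The genes in this part were chosen after their values were seen, and no explanation was tested for them. The largest fall with Ras[V12] and lacZ RNAi among these was that of CG17633, 25.4-fold (log2 fold change -4.66 ± 0.16 SE, 4 against 2 arrays), followed by CG15254 at 9.71-fold (-3.28 ± 0.36) and CG9672 at 8.96-fold (-3.16 ± 0.24). All 3 rose when Dph5 RNAi was added to Ras[V12], by 9.08-fold, 11.1-fold and 7.42-fold in that order. lncRNA:alphagamma-element:CR32865, an RNA from a heat shock locus, went the other way, rising 12.1-fold with Ras[V12] (3.60 ± 0.28) and falling 8.67-fold with Dph5 RNAi added (-3.12 ± 0.23), at 2.06 and -2.01 under normexp background. CG6484 was 60.8-fold higher with Dph5 RNAi alone (5.93 ± 0.36), with both lacZ RNAi arrays apart at log2 signals of -1.76 and -3.03, and 18.6-fold higher with Dph5 RNAi and Ras[V12] (4.22 ± 0.29). The antisense RNA asRNA:Eig63F-2 was well above background on all 4 Dph5 RNAi arrays and on 0 of the other 10, which puts it at least 77.9-fold above lacZ RNAi and at least 97.5-fold above Ras[V12] with Dph5 RNAi. Under normexp background its log2 fold change was 2.82 with Dph5 RNAi alone and -2.96 with Ras[V12] under Dph5 RNAi, so the bounds hold only for the signals as background-subtracted by the scanner software. Likewise CG34423 was at least 12.5-fold higher with Ras[V12] than without under lacZ RNAi, but gave a log2 fold change of 0.80 under normexp background.

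Among small RNAs with a snoRNA symbol, which guide or process ribosomal RNA, 3 of 4 rose when Dph5 RNAi was added to Ras[V12]. In that comparison limma called 4672 of all 16964 targets higher. Those that rose were snoRNA:U3:9B, 1.41-fold (0.50 ± 0.12), snoRNA:U3:54Aa, 1.36-fold (0.45 ± 0.11), and snoRNA:Psi28S-2566, 1.22-fold (0.29 ± 0.07), each with 4 against 4 arrays. Both U3 genes carry the symbol of the same RNA, and their probes were not shown to tell them apart. These calls ended on slide 1 alone for snoRNA:U3:9B (0.37) and snoRNA:U3:54Aa (0.39), and on slide 2 alone for snoRNA:Psi28S-2566 (0.16). All 3 also rose with Ras[V12] under Dph5 RNAi, at 0.52 ± 0.12, 0.36 ± 0.11 and 0.81 ± 0.07 in that order, where snoRNA:U3:9B did not pass on slide 2 alone (0.52) and snoRNA:U3:54Aa on neither slide alone (0.36 on each). With Ras[V12] under lacZ RNAi, lncRNA:roX1, an RNA of male dosage compensation, fell 1.83-fold (-0.87 ± 0.10), and lncRNA:Hsromega, a heat shock RNA, 1.58-fold (-0.66 ± 0.14, and -0.40 with the mean of all probes). lncRNA:roX2, the other such RNA of dosage compensation, rose 1.69-fold (0.76 ± 0.19), a call that ended on slide 1 alone (0.81).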
